A study of Mus musculus with 32 samples.

How the data were processed

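Total RNA (100 ng per sample) from the left and right atria of 16 mice was hybridised as biotinylated cDNA to Affymetrix Mouse Gene 1.0 ST arrays, 1 array per atrium, per the labels' protocols. The values analysed are log2 probe set signals as deposited, and per the labels they were made with Affymetrix Expression Console and PLIER, for which no version, role, background correction or filter is stated. The base of the logarithm is not stated either; it was taken from the range of the values, 1.16 to 14.08, since base e or 10 would exceed what a 16-bit scanner records. The method of scaling between arrays is not stated. The array medians differed by at most 0.18 log2, so no further scaling was applied.

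Genotype, side and animal number came from the labels. Of 35512 probe sets, 21789 carried a single gene symbol in the platform's annotation, 1621 carried several and 12102 none, and only the first kind was used. Among 19938 named genes, 999 had several probe sets and were represented by the brightest. Genes whose mean was below 4.48 log2, the 30th percentile of all probe sets, were left out, which left 15219. No array was left out. No duplicate arrays were found, the highest correlation of any pair being 0.9903. All 32 arrays had Xist between 2.87 and 3.80 log2 and Eif2s3y between 7.47 and 8.55; the labels give no sex.

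Both arrays of an animal carry the same animal number, so they were not treated as independent. As a check of the pairing, the deviations of an animal's arrays from their group means correlated at a median of 0.05 (lowest -0.42, highest 0.44), with 7 of 16 animals above 0.1. In Ntg and Mst1 each labelled side mixes high and low levels of the atrial gene Bmp10, as described below. Side differences then enter an animal's 2 deviations with opposite signs, so the check cannot decide the pairing in these genotypes. The lowest value, -0.42, belongs to Mst1 1839. For genotype comparisons the mean of an animal's arrays was used, and for side comparisons the difference of the array labelled right minus that labelled left. Each was fitted with limma (lmFit, then eBayes with a trend) over the 4 genotypes with 4 animals each, and p-values were adjusted by the Benjamini-Hochberg method over all genes, a gene being called at an adjusted p under 0.05. For the side terms that trend runs over a gene's mean difference, not its level, which inflates the SE of a gene with a far larger difference than the others. The tests were two-sided. These p-values measure the spread between these animals. Genotype contrasts were Mst1 against Ntg, dnPI3K against Ntg, dnPI3K-Mst1 against Ntg, Mst1 and dnPI3K, and the non-additivity term (dnPI3K-Mst1 minus Mst1 minus dnPI3K plus Ntg).

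There were 42 gene lists, fixed before the data were examined, as were the groups, the contrasts, the filter and the rule for named genes. They cover cell types and tissues, atrial and sinoatrial identity, electrical, calcium and contractile genes, energy metabolism, stress and protein folding, Hippo, YAP, PI3K and FoxO signalling, apoptosis, cell cycle, immunity, the circadian clock and sex-linked genes. Of 965 list genes 833 were tested. Lists share members, and the same gene may count in several. For 40 lists camera was run with a preset inter-gene correlation of 0.01, again with an estimated correlation, and beside fry, which tests each list without comparing it with other genes; 2 lists with few members (erythroid markers and sex-linked genes) are given as values. No camera call in any comparison held with an estimated correlation. Fry called 14 lists in Mst1 against Ntg, 4 in dnPI3K against Ntg, 20 in dnPI3K-Mst1 against Ntg, 6 in dnPI3K-Mst1 against Mst1, 15 in dnPI3K-Mst1 against dnPI3K and 0 for non-additivity and in the side terms.

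Named genes are, for each genotype comparison, the 8 with the largest rise and the 8 with the largest fall among called genes whose animals do not overlap between the groups, without Xist, Y-linked genes and unnamed models. Added to these are up to 4 called members of each list, those with the largest change, and Stk4, Pik3ca, Nppa, Nppb, Myh7 and Col1a1 in every comparison. Where fewer than 3 genes were called, the 3 with the smallest p are given as values. For the non-additivity and side-difference terms the rule takes the 5 largest called. The text gives a selection of these.

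The procedure was tested on simulated data with 200 changed genes. For Mst1 against Ntg 85.5%, 99.5% and 100% of changes of 0.5, 1 and 2 log2 were recovered, with 7, 11 and 8 false calls. For dnPI3K against Ntg the shares were 82%, 100% and 100% (10, 12 and 6 false calls), for the sides over 4 genotypes 98.5%, 99.5% and 100% (4, 8 and 12), and for the sides in Ntg alone 39%, 99% and 100% (4, 9 and 10). Of 20 lists shifted by 0.3 log2 camera and fry found 20, with 4 other lists called by camera over the 20 simulations. The simulated genes were independent, while oxidative phosphorylation genes had an estimated correlation of 0.41 in Mst1 against Ntg. These counts therefore do not show how often camera wrongly calls a list of correlated genes. In a simulation of sign patterns of the sides, 5 genes shared the commonest pattern without planted genes and 60 with 60 planted.

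Alternatives were quantile normalization, centring each array on its median, the mean of a gene's probe sets, no filter or a filter at the 50th percentile (11382 genes), eBayes without trend or with trend and robust, array weights, all 32 arrays in 1 fit with or without the animal as a random block (consensus correlation 0.119), 1 side only, only the 2 genotypes compared, the range of the animal number or the Y-linked level as covariates, sex-linked genes left out, and each animal left out in turn. Alternatives for linear values were not run, since the values are log2. After the data were seen, 2 were added that leave out the 4 arrays with a mean correlation under 0.97 with the others, or their animals, and for the side terms 2 more, eBayes with the trend over the mean level and camera without trend, which lost 0 of the lists called. For the pair of effects that share Ntg animals, the correlation expected with no effect came from 100 simulations. Versions were R 4.3.3, limma 3.58.1 and, for reading files, the R package data.table (version 1.17.8), with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.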

Results

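Transcript levels were measured in the left and right atria of 16 mice on a mixed C57BL/6 and FVB/N background, with 1 array per atrium and 32 arrays in all. There were 4 animals of each of 4 genotypes: non-transgenic controls (Ntg), mice with a dominant negative phosphoinositide 3-kinase (dnPI3K), mice with the kinase Mst1, and mice with both (dnPI3K-Mst1). PI3K carries insulin and growth factor signals that favour growth and survival of the heart. Mst1, encoded by Stk4, is a kinase of the Hippo pathway, which restrains the coactivator YAP and can promote the death of cardiac myocytes. Genotypes were compared over 15219 genes on the mean of an animal's 2 atria, so each group held 4 animals, a number that limits the precision. The array medians lay between 5.51 and 5.68 log2. In 4 of the 32 arrays the mean correlation with the other arrays was under 0.97: Mst1 1466 left (0.949), dnPI3K 3241 left (0.960), dnPI3K 1507 left (0.968) and Ntg 1662 right (0.969). Sides are given throughout as labelled, because the atrial gene Bmp10 splits the arrays differently from the side labels, as the last comparison shows. Fits on arrays of 1 labelled side therefore mix genotype with side as told by Bmp10, wherever their counts or values are given.

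Stk4 was higher in each of the 8 animals labelled as carrying Mst1 than in each of the 8 others. Its mean was 7.54 ± 0.11 log2 (SD, n = 4) in Ntg, 7.61 ± 0.13 in dnPI3K, 8.25 ± 0.09 in Mst1 and 8.33 ± 0.11 in dnPI3K-Mst1. Pik3ca, the gene of the catalytic subunit p110 alpha, averaged 9.11 ± 0.25 in Ntg, 9.73 ± 0.30 in Mst1, 10.04 ± 0.09 in dnPI3K and 10.27 ± 0.13 in dnPI3K-Mst1. It rose 1.89-fold in dnPI3K against Ntg (adjusted p = 0.00028) and 1.53-fold in Mst1 against Ntg (adjusted p = 0.0014). Pik3r1, the gene of its regulatory partner, averaged 9.45 ± 0.29, 8.60 ± 0.09, 9.14 ± 0.04 and 8.89 ± 0.13 in Ntg, Mst1, dnPI3K and dnPI3K-Mst1. The labels do not say which part of PI3K the dnPI3K transgene carries, so neither gene need report it.

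**Figure D1:**
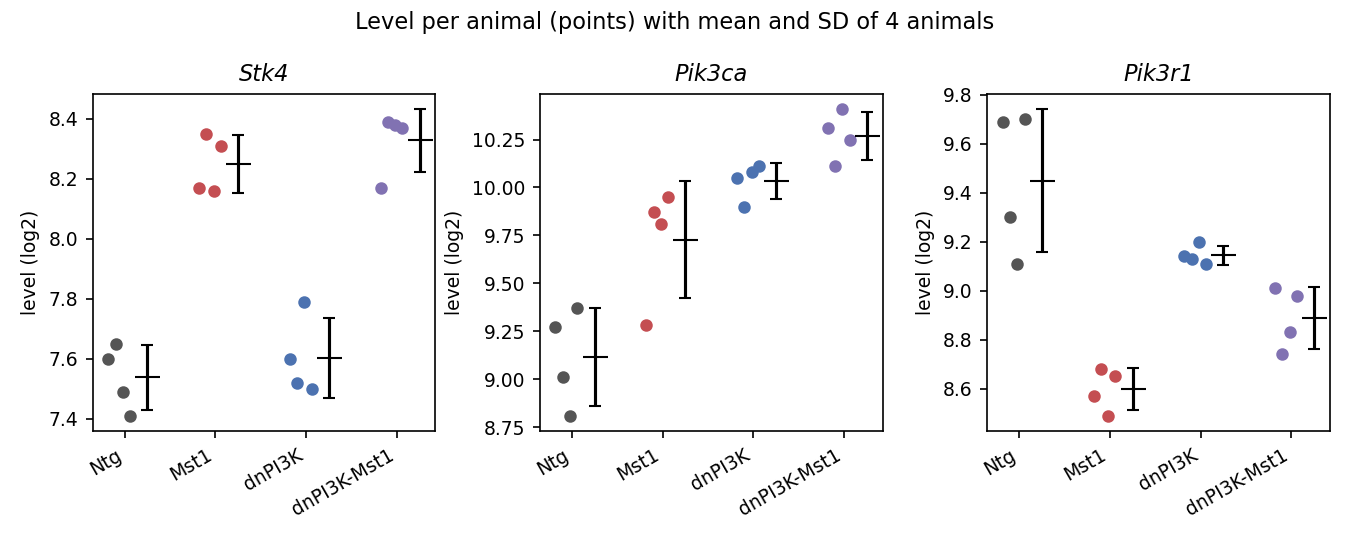
Level of Stk4, Pik3ca and Pik3r1 (log2, mean of an animal's 2 atria) in each of the 16 animals, with the mean and SD of each genotype as a bar and whiskers beside the points. The 8 animals with the Mst1 transgene have Stk4 at 8.16 or higher, and the 8 without it have 7.79 or lower.

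The first comparison asked what the Mst1 transgene alone did to the atria. Thbs4, a matrix protein of injured heart muscle, rose 15.4-fold in Mst1 against Ntg (3.95 ± 0.12 log2, SE, n = 4 against 4). Ckm, the muscle creatine kinase that buffers ATP, fell 11.9-fold (-3.57 ± 0.15). The stress-induced transcription factor Atf3 rose 11-fold, the deubiquitinase Uchl1 6.88-fold, the ERBB receptor ligand Nrg1 6.79-fold and the smooth muscle gene Cnn1 5.91-fold, with Fam171b, Muc15 and Ccdc68 also up by 7.45-fold, 6.29-fold and 5.24-fold. The carboxylesterase Ces1d fell 8.24-fold and Dgat2, which completes triglyceride synthesis, 6.01-fold. Itgb6, Slc36a2, Lrtm1, Asb14 and Car14 fell 5.25-fold, 4.87-fold, 4.73-fold, 4.64-fold and 4.6-fold. Dgat2 and Slc36a2 are also adipocyte markers, and Ntg 1301 carries fat genes on its array labelled left, which may enlarge their falls. In all, limma called 4084 genes, 1919 higher and 2165 lower, of which 173 and 194 changed by at least 2-fold. Which direction is the commoner depends on Mst1 1466 and on the arrays used: 2669 were higher and 2137 lower without that animal, 2491 and 2067 without the 4 animals whose arrays stood apart, 3143 and 2646 with array weights, 1803 and 1488 on arrays labelled right, but 745 and 1384 on arrays labelled left.

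Genes of mitochondrial energy supply fell almost as a block. All 24 measured members of the tricarboxylic acid cycle list fell, as did 71 of 73 for oxidative phosphorylation and 29 of 34 for fatty acid oxidation, and none of these lists held a member that rose. Adjusted over the list alone, the numbers lower were 24, 71 and 30, with 1 oxidative phosphorylation gene higher. The median changes were -0.73, -0.65 and -0.86 log2, with Cox7a1 at -1.65 ± 0.13, Sdhb at -1.03 ± 0.09, Acaa2 at -1.43 ± 0.12 and Echs1 at -1.22 ± 0.09. Camera gave adjusted p = 6.5e-21, 2.1e-35 and 4.7e-21 for the 3 lists, and adjusted p = 0.17 for each with an estimated correlation. Glycolysis was divided: 4 of 22 members rose and 9 fell (camera adjusted p = 0.13). Slc2a1, the basal glucose transporter, rose by 1.23 ± 0.14, while Slc2a4, its insulin-responsive counterpart, changed by -1.19 ± 0.10. Across the same animals the sarcomere and Z-disc list, a measure of myocyte content, had a median of -0.10, with 3 of 34 members higher and 9 lower (camera adjusted p = 0.13).

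Stress genes of the heart rose: 16 of 19 members of that list were higher and none lower (18 higher adjusted over the list alone), among them Nes (2.39 ± 0.25), Xirp2 (2.05 ± 0.16), Tnfrsf12a (1.77 ± 0.23) and the natriuretic peptide Nppb (1.51 ± 0.16). Camera gave adjusted p = 1.1e-12, and adjusted p = 0.17 with an estimated correlation. Nppa, already abundant in atria, was at 0.13 ± 0.06 (adjusted p = 0.091) and Myh7, the fetal myosin, at -0.08 ± 0.15 (adjusted p = 0.76), neither of them called. Of 45 collagen and matrix genes 20 rose and none fell (26 higher adjusted over the list alone), led by Thbs4, Thbs1 (2.18 ± 0.27), Ltbp2 (1.87 ± 0.16) and Col12a1 (1.82 ± 0.13). The camera adjusted p was 2.1e-10, with adjusted p = 0.6 with an estimated correlation. Col1a1 was at 0.51 ± 0.26 (adjusted p = 0.16), not called. In the unfolded protein response list 16 of 29 genes rose and 4 fell, with Creld2 at 0.88 ± 0.11 and Herpud1 at -0.77 ± 0.11 (camera adjusted p = 0.00031, adjusted p = 0.51 with an estimated correlation). Immediate early genes had 8 of 26 higher and 1 lower (camera adjusted p = 0.0067, adjusted p = 0.83 with an estimated correlation), and heat shock genes 6 of 23 higher and 2 lower, with Hspb1 at 1.58 ± 0.24 (0.041, and adjusted p = 0.83 with an estimated correlation).

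YAP and TEAD target genes, which the Hippo kinases are known to hold down, were higher where they changed. Of 23 measured targets 9 rose and none fell (11 higher adjusted over the list alone), including Ccn2 (1.63 ± 0.20), Nt5e (1.60 ± 0.14), Ccn1 (1.56 ± 0.30) and Tgfb2 (1.11 ± 0.20). The list had a median of 0.20 and a camera adjusted p = 0.00016, with adjusted p = 0.65 with an estimated correlation. The Hippo pathway members had 7 of 23 higher and 2 lower, with Stk38 at 0.58 ± 0.09 and Tead1 at -0.48 ± 0.15, or -0.25 without Mst1 1466 (camera adjusted p = 0.041, adjusted p = 0.83 with an estimated correlation). In every comparison that list includes Stk4, the gene of Mst1 itself, which averaged 7.54 log2 in Ntg and 8.25 in Mst1. Apoptosis genes went both ways, 5 of 33 higher and 5 lower (camera adjusted p = 0.73): the survival gene Bcl2 rose by 0.87 ± 0.11, Gadd45g rose by 1.26 ± 0.28, and Bcl2l11 and Aifm1 changed by -0.61 ± 0.12 and -0.71 ± 0.10.

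The electrical genes of the atrium fell in large part. Of 44 ion channel and gap junction genes 23 fell and 4 rose (24 lower and 4 higher adjusted over the list alone), with the transient outward channel Kcnd2 at -2.17 ± 0.15, the small conductance channel Kcnn2 at -1.46 ± 0.13, the atrial connexin Gja5 at -1.43 ± 0.13 and the sodium channel subunit Scn4b at -1.16 ± 0.19. Camera gave adjusted p = 1.6e-06, and adjusted p = 0.17 with an estimated correlation. Atrial myocardium markers had 8 of 15 lower and 1 higher (camera adjusted p = 0.00089, adjusted p = 0.47 with an estimated correlation), with Kcnj3 at -1.04 ± 0.10 and Kcna5 at -0.83 ± 0.11. Among calcium handling genes Hrc, a calcium-binding protein of the sarcoplasmic reticulum, changed by -1.69 ± 0.12 and its pump Atp2a2 by -0.33 ± 0.09 (-0.21 without Mst1 1466), and the list had 1 of 22 higher and 5 lower (camera adjusted p = 0.24).

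Markers of other cells moved unevenly in Mst1. Adipocyte markers had 6 of 11 lower (camera adjusted p = 0.0014, adjusted p = 0.74 with an estimated correlation), but Ntg 1301 carries fat genes on its array labelled left (Adipoq at 7.85, against a median of 3.90 over 32 arrays), and without that animal 3 were lower (camera adjusted p = 0.013). Endothelial markers had 6 of 15 lower and 1 higher, with Kdr at -0.79 ± 0.13 and Tek at -0.79 ± 0.10 (0.02, and adjusted p = 0.83 with an estimated correlation), and mesothelium markers 4 of 11 lower (0.041, and adjusted p = 0.83 with an estimated correlation). Fibroblast markers had 5 of 15 higher and 3 lower, with Meox1 at 1.94 ± 0.25 and Scara5 at -1.13 ± 0.10 (0.5). Macrophage and monocyte markers had 2 of 25 higher and 3 lower (0.87), and Lgals3, which myocytes under stress can also express, rose by 1.71 ± 0.12. Smooth muscle and pericyte markers had 4 of 14 higher and 5 lower, with a median of -0.09 and a mean of 0.16 (0.95).

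**Figure D2:**
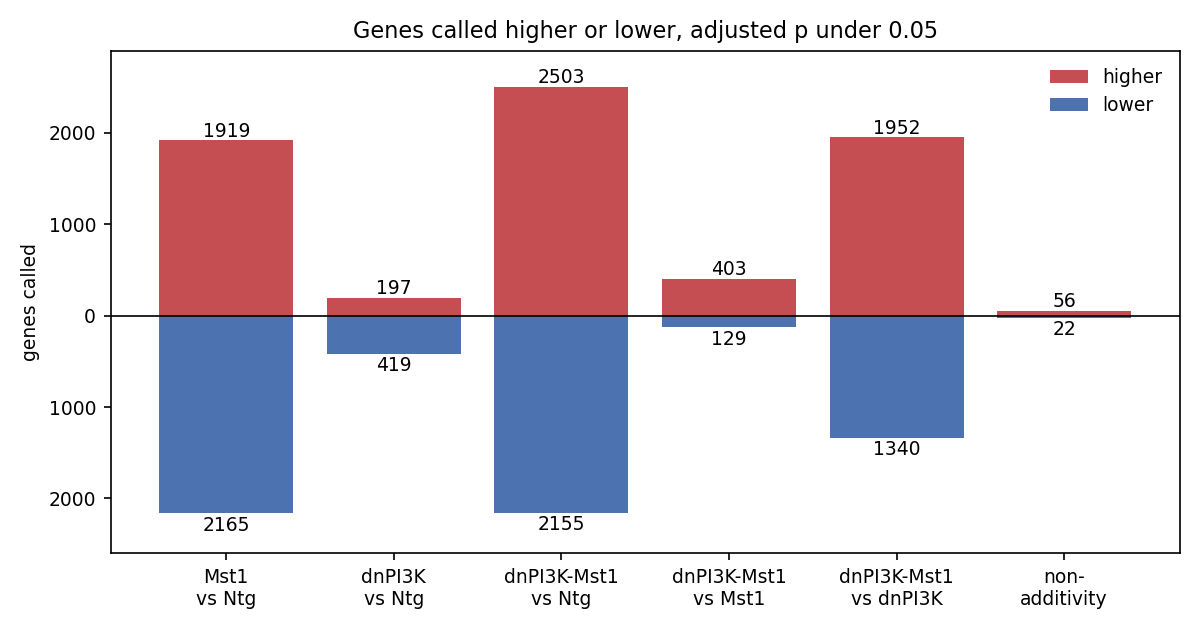
Number of genes called higher (upward bars) and lower (downward bars) in each genotype comparison and for the non-additivity term, of 15219 genes tested with 4 animals per genotype. Comparisons of animals that differ in the Mst1 transgene give 3292 to 4658 genes, and those that differ in dnPI3K alone 532 and 616.

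The dnPI3K transgene without the Mst1 transgene was examined in dnPI3K against Ntg, and PI3K activity itself was not measured. Adamts8, a secreted metalloprotease, rose 4.34-fold (2.12 ± 0.23 log2, SE, n = 4 against 4) and Nrg1 3.35-fold (1.75 ± 0.18). The potassium channel gene Kcnh7 rose 2.49-fold, the galectin Lgals3 2.46-fold, Dusp4, a phosphatase that ends MAP kinase signalling, 2.31-fold, Ndnf 2.19-fold, and Phlda1 and the monocarboxylate transporter Slc16a7 2.06-fold each. Lrtm1 fell 3.59-fold (-1.84 ± 0.20), Casq1, a calcium buffer of the sarcoplasmic reticulum, 2.72-fold and Asns, which makes asparagine, 2.6-fold. Igsf1, Cpne5, Slc17a7, Mrgprh and Ankrd23 fell 2.65-fold, 2.52-fold, 2.46-fold, 2.43-fold and 2.39-fold. Nppb rose 1.81-fold, while Nppa (0.05 ± 0.06, adjusted p = 0.71), Myh7 (0.09 ± 0.15, adjusted p = 0.82) and Col1a1 (-0.10 ± 0.26, adjusted p = 0.9) were not called.

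The mitochondrial lists had negative medians in dnPI3K, smaller in size than in Mst1, a difference that was not tested. Most of their members were not called over all genes. Among oxidative phosphorylation genes 12 of 73 fell over all genes and 44 adjusted over the list alone, with a median of -0.27 and Cox7a1 at -0.61 ± 0.13 and Ndufs4 at -0.43 ± 0.09. The tricarboxylic acid cycle had 7 of 24 lower (17 lower and 1 higher adjusted over the list alone), fatty acid oxidation 3 of 34 (12) and glycolysis 5 of 22 (12 lower and 1 higher), with medians of -0.27, -0.23 and -0.22. Camera gave adjusted p = 6.5e-21, 1.5e-09, 5.8e-06 and 0.00044 for the 4 lists, and adjusted p = 0.68, 0.68, 0.73 and 0.73 with an estimated correlation. YAP and TEAD targets had 4 of 23 higher (9 adjusted over the list alone), with Ccn2 at 0.88 ± 0.20 and Nt5e at 0.86 ± 0.14 (camera adjusted p = 0.00017, adjusted p = 0.73 with an estimated correlation). Of the PI3K and insulin signalling members 4 of 30 rose, namely Pik3ca, Igf1r (0.68 ± 0.17), Igf1 (0.59 ± 0.14) and Irs1 (0.50 ± 0.12), and none fell (camera adjusted p = 0.16). FoxO target and atrophy genes, which PI3K signalling is known to repress, had 2 of 27 higher and 1 lower (0.2). Ion channel genes had 2 of 44 higher and 6 lower (0.044, and adjusted p = 0.75 with an estimated correlation) and calcium handling 5 of 22 lower (0.023, and adjusted p = 0.73 with an estimated correlation). Cytokines, chemokines and complement had 2 of 30 higher, Vcam1 (0.60 ± 0.12) and Il6st (0.38 ± 0.10) (0.0049, and adjusted p = 0.73 with an estimated correlation), and fibroblast markers 2 of 15 higher, Dpep1 (0.65 ± 0.13) and Pdgfra (0.50 ± 0.11) (0.029, and adjusted p = 0.75 with an estimated correlation). Adipocyte markers had a median of -0.47 and 1 of 11 lower (0.0021, and adjusted p = 0.73 with an estimated correlation). Without Ntg 1301, which carries fat genes, their median was -0.26 and camera did not call them (adjusted p = 0.051). Of 34 antioxidant and metallothionein genes 2 fell, Prdx3 (-0.47 ± 0.10) and Gsta4 (-0.40 ± 0.11) (0.029, and adjusted p = 0.68 with an estimated correlation). Heat shock genes had 2 of 23 lower (0.0073, and adjusted p = 0.91 with an estimated correlation) and skeletal muscle markers 2 of 10 lower, Myl1 (-0.73 ± 0.17) and Atp2a1 (-0.53 ± 0.09) (0.026, and adjusted p = 0.6 with an estimated correlation).

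The calls in dnPI3K against Ntg were 616, 197 higher and 419 lower, but on arrays labelled right alone 179 were higher and 160 lower. Arrays labelled right mix high and low Bmp10 in Ntg but not in dnPI3K, so that fit also mixes genotype with side. The count depended on single animals: it was 378 without Ntg 1662, 398 without dnPI3K 1507, 405 without dnPI3K 3241 and 1013 without Mst1 1466, which enters through the shared estimate of spread. Centring each array on its own median gave 21.3% of calls higher in place of 32%.

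Animals with both transgenes were set against Ntg. Nrg1 rose 12.8-fold in dnPI3K-Mst1 (3.68 ± 0.18 log2, SE, n = 4 against 4), Thbs4 11.9-fold, Thbs1 8.12-fold, the vasoconstrictor peptide gene Edn1 7.63-fold and Sfrp2, a secreted Wnt-binding protein, 7.47-fold. Atf3, Pak3 and Sprr1a rose 6.38-fold, 4.86-fold and 4.85-fold. Ckm fell 16.5-fold (-4.05 ± 0.15) and Ckmt2, the mitochondrial creatine kinase, 8.75-fold, followed by Ces1d (7.06-fold), Itgb6 (5.83-fold), Lrtm1 (5.01-fold), Kcnd2 (4.99-fold), Hrc (4.96-fold) and the actin-capping gene Tmod4 (4.85-fold). Nppb rose 2.3-fold and Col1a1 2.13-fold. Of 15219 genes 2503 were higher and 2155 lower, 4658 in all, and centring each array on its median gave 42.7% higher in place of 53.7%. The balance also turned with quantile normalization (2279 higher and 2606 lower) and on arrays labelled left alone (1141 and 1276).

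Matrix genes rose in nearly the whole list: 40 of 45 were higher in dnPI3K-Mst1 than in Ntg and none lower (42 adjusted over the list alone), with Thbs1 at 3.02 ± 0.27, Ltbp2 at 2.20 ± 0.16 and Col12a1 at 2.08 ± 0.13 (camera adjusted p = 1.1e-18, adjusted p = 0.34 with an estimated correlation). Fibroblast markers had 8 of 15 higher and 2 lower (0.011, and adjusted p = 0.67 with an estimated correlation), smooth muscle and pericyte markers 6 of 14 higher and 1 lower (0.035, and adjusted p = 0.66 with an estimated correlation) and macrophage and monocyte markers 12 of 25 higher and 1 lower (0.0031, and adjusted p = 0.7 with an estimated correlation). YAP and TEAD targets had 17 of 23 higher (18 adjusted over the list alone), with Ccn1 at 2.17 ± 0.30 (camera adjusted p = 8.4e-08, adjusted p = 0.37 with an estimated correlation), and Hippo members 12 of 23 higher and 1 lower (0.0034, and adjusted p = 0.67 with an estimated correlation). Immediate early genes had 15 of 26 higher and 1 lower, with Egr1 at 1.39 ± 0.35 and Egr2 at 1.83 ± 0.45, or 0.91 and 1.16 without dnPI3K-Mst1 1647 (5.6e-05, and adjusted p = 0.67 with an estimated correlation), and stress genes 14 of 19 higher (1.1e-07, and adjusted p = 0.39 with an estimated correlation).

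Energy genes fell in this comparison too, with 72 of 73 oxidative phosphorylation genes, 23 of 24 of the tricarboxylic acid cycle and 29 of 34 of fatty acid oxidation lower and none higher (72, 23 and 30 adjusted over the list alone). The medians were -0.86, -0.85 and -0.93, and Cox7a1 changed by -2.19 ± 0.13. Camera gave adjusted p = 1.6e-47, 3.9e-22 and 5.1e-23, and adjusted p = 0.17 for each with an estimated correlation. Ion channels had 21 of 44 lower and 4 higher (5.7e-05, and adjusted p = 0.34 with an estimated correlation), calcium handling 10 of 22 lower and 4 higher (0.028, and adjusted p = 0.67 with an estimated correlation), with Ryr2 at -0.48 ± 0.17, and the sarcomere and Z-disc list 14 of 34 lower and 2 higher (0.0045, and adjusted p = 0.7 with an estimated correlation). Atrial myocardium markers had 8 of 15 lower and 2 higher (0.0013, and adjusted p = 0.39 with an estimated correlation), and adipocyte markers 3 of 11 lower (0.024, and adjusted p = 0.7 with an estimated correlation), a call that camera did not make without Ntg 1301 (adjusted p = 0.15).

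The comparison of dnPI3K-Mst1 with Mst1 asked what the dnPI3K transgene adds to atria that already carry Mst1. Sfrp2 rose 3.19-fold (1.67 ± 0.19 log2, SE, n = 4 against 4). The iron exporter Slc40a1 rose 2.47-fold and Hamp, the gene of hepcidin, which removes that exporter from cell membranes, 2.3-fold. The BMP antagonist Chrdl1 and the mesothelial gene Lrrn4 rose 2.28-fold each, Fmod 2.25-fold, Ccn5 2.24-fold and Svep1 2.16-fold. Ckmt2 fell 1.95-fold, B3galt2 1.9-fold, Ankrd23 and the opsin Opn3 1.86-fold each, and Plppr5, Nap1l5, Marchf11 and Slc24a2 1.76-fold, 1.7-fold, 1.7-fold and 1.69-fold. A dimmer probe set of Marchf11 was at -0.13, against -0.76 for the brighter one used here.

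Some matrix genes and some markers of non-myocyte cells were higher with both transgenes than with Mst1 alone, though most members of each list were not called. Fry called the endothelial (adjusted p = 0.016) and smooth muscle lists (adjusted p = 0.012), but not matrix (0.086), fibroblast (0.063), macrophage (0.086) or mesothelium (0.097). Of 45 matrix genes 10 rose and none fell (22 higher and 1 lower adjusted over the list alone), with the fibronectin gene Fn1 at 1.00 ± 0.21, Eln at 0.92 ± 0.23 and Thbs2 at 0.82 ± 0.17 (camera adjusted p = 9.7e-11, adjusted p = 0.4 with an estimated correlation). Endothelial markers had 7 of 15 higher (10 adjusted over the list alone), with Vwf at 0.78 ± 0.16, Tie1 at 0.56 ± 0.10 and Tek at 0.55 ± 0.10 (1.7e-09, and adjusted p = 0.32 with an estimated correlation). Smooth muscle and pericyte markers had 4 of 14 higher, with Itga8 at 1.08 ± 0.19 and Pdgfrb at 0.58 ± 0.12 (7e-06, and adjusted p = 0.28 with an estimated correlation), and fibroblast markers 4 of 15, with Islr at 0.60 ± 0.12 (0.00027, and adjusted p = 0.4 with an estimated correlation). Macrophage and monocyte markers had 3 of 25 higher over all genes and 11 adjusted over the list alone, with the receptor Csf1r at 0.68 ± 0.15 (7.1e-07, and adjusted p = 0.4 with an estimated correlation). Mesothelium markers had 2 of 11 higher (1.5e-05, and adjusted p = 0.4 with an estimated correlation) and interferon-stimulated genes 2 of 24, Ifit2 (0.44 ± 0.09) and Ddx58 (0.37 ± 0.08) (7e-06, and adjusted p = 0.32 with an estimated correlation). MHC class II had none of 7 called and a median of 0.45 (0.011, and adjusted p = 0.41 with an estimated correlation). No member was called among 11 adipocyte (0.11), 8 T and B lymphocyte (0.79) and 14 cardiac neuron and glia markers (0.92), with medians of 0.30, 0.05 and 0.03. The adipocyte value rests in part on dnPI3K-Mst1 1650, whose array labelled right carries fat genes (Adipoq at 7.79, against a median of 3.90 over 32 arrays), and camera gave adjusted p = 0.72 without that animal.

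The oxidative phosphorylation list had a median of -0.21, with 7 of 73 members lower and 66 not called (15 lower adjusted over the list alone). Cox7a1 was at -0.54 ± 0.13 (camera adjusted p = 1.8e-20 for the list, adjusted p = 0.32 with an estimated correlation). None of 24 tricarboxylic acid cycle and 34 fatty acid oxidation genes was called, with medians of -0.11 and -0.09 (0.0045 and 0.011, and adjusted p = 0.64 and 0.66 with an estimated correlation). The stress genes had a median of -0.22, with Mt2 at -0.63 ± 0.12 the only 1 of 19 called (0.00085, and adjusted p = 0.48 with an estimated correlation), and none of 23 heat shock genes was called at a median of -0.23 (7.4e-07, and adjusted p = 0.41 with an estimated correlation). The sarcomere and Z-disc list had none of 34 called and a median of -0.08 (0.011, and adjusted p = 0.66 with an estimated correlation). Gja5, which fell in Mst1 alone, rose here by 0.68 ± 0.13.

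In this comparison 532 genes were called, 403 higher and 129 lower, and quantile normalization gave 64.2% higher in place of 75.8%. The range of the animal number nearly separates these 2 genotypes. With that range as a factor 310 genes were called, and 211 of these were among the 532. The count was 249 without Mst1 1839, 278 without dnPI3K-Mst1 1647 and 314 without dnPI3K-Mst1 1509, and 903 without the 4 animals whose arrays stood apart, a choice made after seeing the data. The balance of directions rests on Mst1 1466: without it 434 were higher and 331 lower (56.7% higher), and without the 4 animals 500 and 403 (55.4%).

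**Figure D3:**
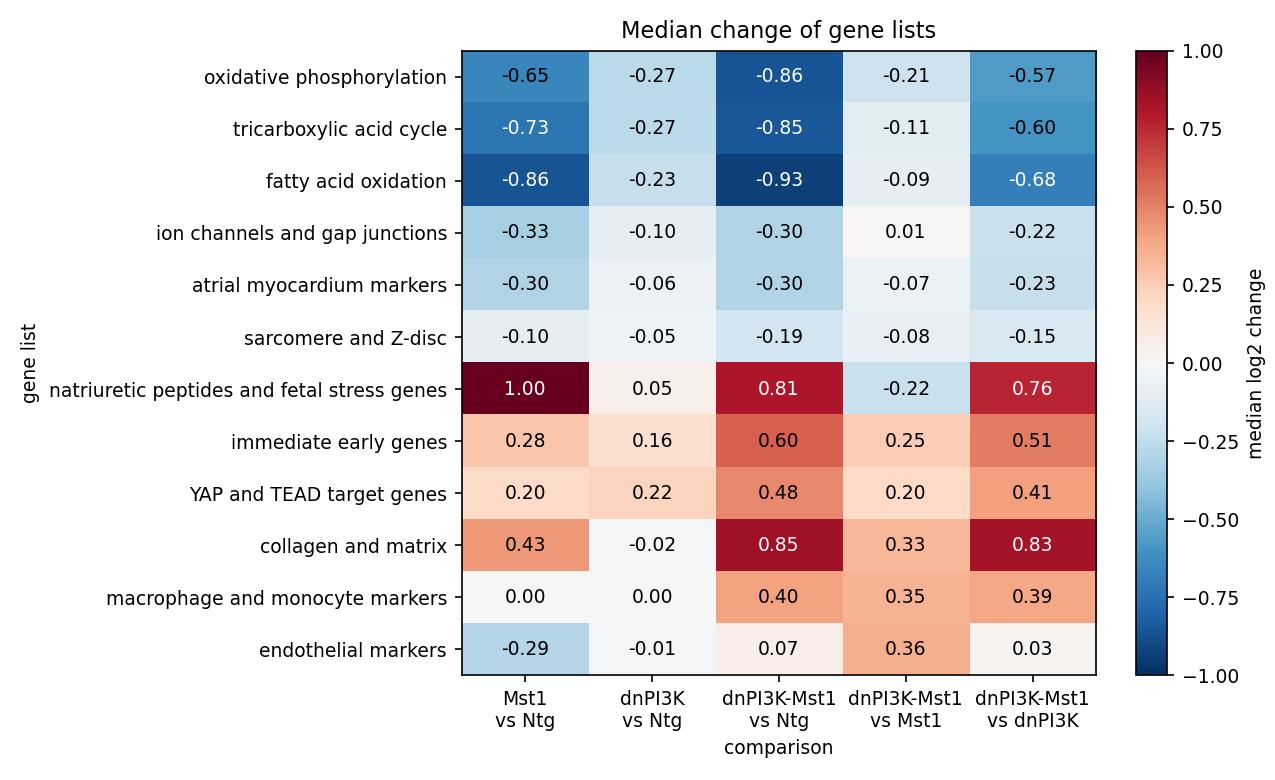
Median log2 change of 12 gene lists in the 5 genotype comparisons, drawn as colour and printed in each cell, with 4 animals per genotype. The 3 mitochondrial lists are negative in all 5 comparisons, and collagen and matrix genes are at 0.33 or above in all but dnPI3K against Ntg.

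The Mst1 transgene was also examined on the dnPI3K background, in dnPI3K-Mst1 against dnPI3K. Thbs4 rose 9.01-fold (3.17 ± 0.12 log2, SE, n = 4 against 4), Thbs1 8.7-fold, the actin-binding gene Xirp2 5.57-fold, the matrix genes Aspn and Cilp 5.07-fold and 5.03-fold, Uchl1 5.01-fold, Col12a1 4.81-fold and Tagln, a smooth muscle actin-binding gene, 4.77-fold. Ckm fell 10.4-fold (-3.38 ± 0.15), Ces1d 6.03-fold, the desaturase Scd4 6-fold, Kcnh7 4.75-fold, Lmod3 4.58-fold, Asb14 4.5-fold, Ckmt2 4.31-fold and Inmt 4.12-fold. Col1a1 rose 2.28-fold, and Nppb, at 0.35 ± 0.16, was not called (adjusted p = 0.15). There were 3292 calls, 1952 higher and 1340 lower, or 1712 and 1663 with quantile normalization.

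Matrix genes were the broadest rise, 44 of 45 higher and none lower with the same number adjusted over the list alone (camera adjusted p = 2.3e-23, adjusted p = 0.25 with an estimated correlation). Oxidative phosphorylation had 71 of 73 lower, the tricarboxylic acid cycle 23 of 24 and fatty acid oxidation 29 of 34, with medians of -0.57, -0.60 and -0.68 (72, 23 and 31 adjusted over the list alone). Camera gave adjusted p = 2.5e-44, 1.1e-20 and 3.8e-24, and adjusted p = 0.16 for each with an estimated correlation. Stress genes had 11 of 19 higher (1.9e-06, and adjusted p = 0.46 with an estimated correlation), YAP and TEAD targets 14 of 23 (2.2e-05, and adjusted p = 0.5 with an estimated correlation), immediate early genes 14 of 26 (4e-05, and adjusted p = 0.6 with an estimated correlation) and Hippo members 11 of 23 (0.0015, and adjusted p = 0.6 with an estimated correlation), none of them with a member lower. The unfolded protein response had 8 of 29 higher and 1 lower (0.0076, and adjusted p = 0.6 with an estimated correlation), and the sarcomere and Z-disc list 3 of 34 higher and 11 lower, with Myl3 at -0.95 ± 0.21 (0.0021, and adjusted p = 0.72 with an estimated correlation). Myl3 is also a ventricular marker, and the ventricular gene Myl2 reached 10.70 on dnPI3K 1648 left, against a median of 5.21 over 32 arrays. Whether this bears on the change of Myl3 was not tested. Cell cycle genes had 5 of 28 higher, with Top2a at 0.70 ± 0.22 (its dimmer probe set was at -0.04) and Ccnd1 at 0.66 ± 0.15 (0.0065, and adjusted p = 0.77 with an estimated correlation). MHC class II had 3 of 7 higher, with Cd74 at 0.89 ± 0.22 (0.052). Ion channels had 15 of 44 lower and 5 higher (0.00014, and adjusted p = 0.36 with an estimated correlation), with Cacna2d2, a calcium channel subunit, at 1.53 ± 0.12 and Kcnip2, a partner of Kcnd2, at -1.34 ± 0.21. Atrial myocardium markers had 6 of 15 lower (0.0003, and adjusted p = 0.36 with an estimated correlation). Igf1 changed by -1.13 ± 0.14. Macrophage and monocyte markers had 7 of 25 higher and 1 lower (0.004, and adjusted p = 0.72 with an estimated correlation), and smooth muscle and pericyte markers 6 of 14 higher and 1 lower (0.0045, and adjusted p = 0.39 with an estimated correlation). Endothelial, adipocyte and mesothelium markers and heat shock genes, which camera called in Mst1 against Ntg, were not called here (0.83, 0.46, 0.57 and 0.19).

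Both estimates of the Mst1 effect, which share no animals, correlated across genes at Pearson r = 0.81 (Spearman 0.70), and 1191 genes were higher and 1097 lower in both, where independent lists of these sizes would share 246.1 and 190.6. Only 9 genes were called in opposite directions. The matching pair for dnPI3K, without and with Mst1, correlated at r = 0.33 (Spearman 0.31), with 59 genes higher and 39 lower in both against 5.2 and 3.6, and 1 opposite. Genes are not independent replicates, so no p-value is attached to these correlations. The effects of Mst1 and of dnPI3K against the same Ntg animals correlated at r = 0.44, where unchanged groups sharing controls gave r = 0.50 in simulation. The covariance was 0.0285 against 0.00562 simulated, and with the Ntg animals divided between the effects r averaged 0.32 (0.27 to 0.38 over 6 ways). For these effects 97 genes were higher and 320 lower in both and 41 were called in opposite directions, but the shared Ntg animals also bear on these counts.

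The test of non-additivity asked where the double transgenic departs from the sum of both single effects. Adamts8 averaged 6.26 ± 0.40 log2 (SD, n = 4) in Ntg, 7.54 ± 0.38 in Mst1, 8.38 ± 0.55 in dnPI3K and 7.48 ± 0.10 in dnPI3K-Mst1, a departure of -2.18 ± 0.32 (SE, adjusted p = 0.0023) from the sum. Itga8 lay 1.32 ± 0.27 above the sum. Plet1 lay below it (-1.38 ± 0.24, but 0.08 on arrays labelled left alone), as did Nppb (-1.16 ± 0.23, adjusted p = 0.022), Lgals3 (-1.27 ± 0.16), Nt5e (-1.14 ± 0.19) and Mt2 (-0.85 ± 0.18). Slc36a2 (1.18 ± 0.23), Notch3 (0.83 ± 0.16) and the endothelin receptor gene Ednrb (0.83 ± 0.14) lay above it. Slc36a2 is an adipocyte marker, at 6.60 in dnPI3K-Mst1 1650 against a mean of 5.67 in the other animals of that genotype. That animal and Ntg 1301 each have 1 array that carries fat genes. Both genotypes enter the term with a plus sign, so fat tissue may add to this departure. Among the 78 genes called, 56 were above the sum and 22 below, but for 11 of the 56 the sum lies below 4.48 log2, the level under which genes were left out, so the floor of the signal alone can produce a departure above it. The split was 116 and 91 without Mst1 1466, 49 and 44 without the animals whose arrays stood apart, and 11 and 13 on arrays labelled right. Camera called 15 lists for this term, none of them with an estimated correlation. Among these, collagen and matrix had a median of 0.42 with none of 45 called (camera adjusted p = 6e-06, adjusted p = 0.63 with an estimated correlation), endothelial markers 0.34 with none of 15 (1.5e-05, and adjusted p = 0.47 with an estimated correlation), and stress genes -0.31 with 2 of 19 called, both below (1.5e-05, and adjusted p = 0.47 with an estimated correlation). Without Mst1 1466 the count was 207.

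**Figure D4:**
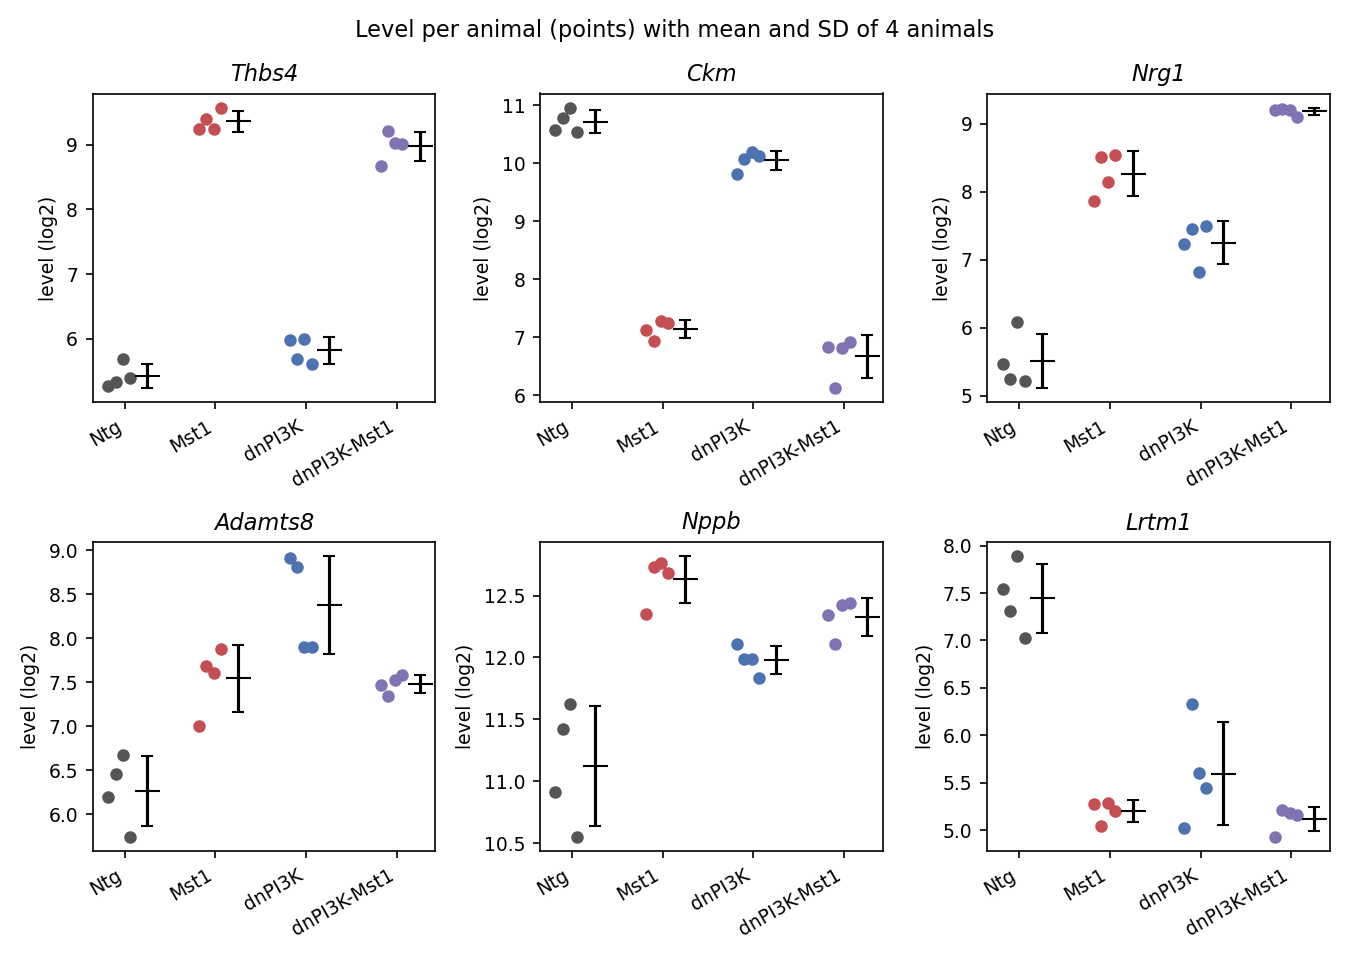
Level of 6 genes (log2, mean of an animal's 2 atria) in each of the 16 animals, grouped by genotype, with the mean and SD beside the points. Thbs4 and Ckm separate the animals with and without Mst1, and Adamts8 averages 8.38 in dnPI3K and 7.48 in dnPI3K-Mst1.

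Sides were compared within animals. Between arrays labelled right and left limma called no gene in Ntg (293 at an unadjusted p under 0.05) and none over the mean of the 4 genotypes (1237 at an unadjusted p under 0.05). Bmp10, which adult mice express in the right atrium, differed by 5.87 to 8.78 log2 between the atria of every animal, but the array labelled left held the higher level in 13 of 16 animals and the array labelled right in 3, Ntg 1301, Ntg 1662 and Mst1 1839. Its mean difference, right minus left as labelled, was -4.98 ± 1.37 (SE within genotypes, n = 16). Limma gave an SE of 5.15 and adjusted p = 0.89, because its trend runs over mean differences and Bmp10 lies far from the next gene (-2.63). With the trend over the mean level, chosen after seeing the data, the SE was 1.09 and adjusted p = 0.077, still not called. Of 15 sinoatrial node genes 7 were higher on the side of Bmp10 in at least 14 animals and 3 in 9 to 13, while 4 were higher there in 3 to 7 animals and 1 in at most 2. Cacna1d, Cpne5, Shox2 and Vsnl1 were each higher on that side in 16 of 16 animals, by a median of 0.75, 0.67, 0.44 and 0.65, and Hamp in 15; these genes were picked from the fixed lists after their values were seen. Smallest p-values over the mean of the genotypes belonged to Cntn2 (-0.50 ± 0.08, adjusted p = 0.11), Thy1 (0.35 ± 0.07, adjusted p = 0.17) and Vsnl1 (-0.60 ± 0.12, adjusted p = 0.17), none of them called, though Cntn2 was the 1 gene called with no trend or with the trend over the mean level. The list of left and right atrial identity genes had a median of -0.15 (camera adjusted p = 3.1e-05, adjusted p = 0.39 with an estimated correlation), sinoatrial node markers -0.21 (3.1e-07, and adjusted p = 0.13 with an estimated correlation), mesothelium markers 0.23 (1e-04, and adjusted p = 0.49 with an estimated correlation) and immediate early genes 0.23 (1.6e-11, and adjusted p = 0.47 with an estimated correlation). In the fit with the animal as block 113 genes were called over the mean of the genotypes, and without Mst1 1839 the paired comparison called 277, without Ntg 1301 it called 2.

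**Figure D5:**
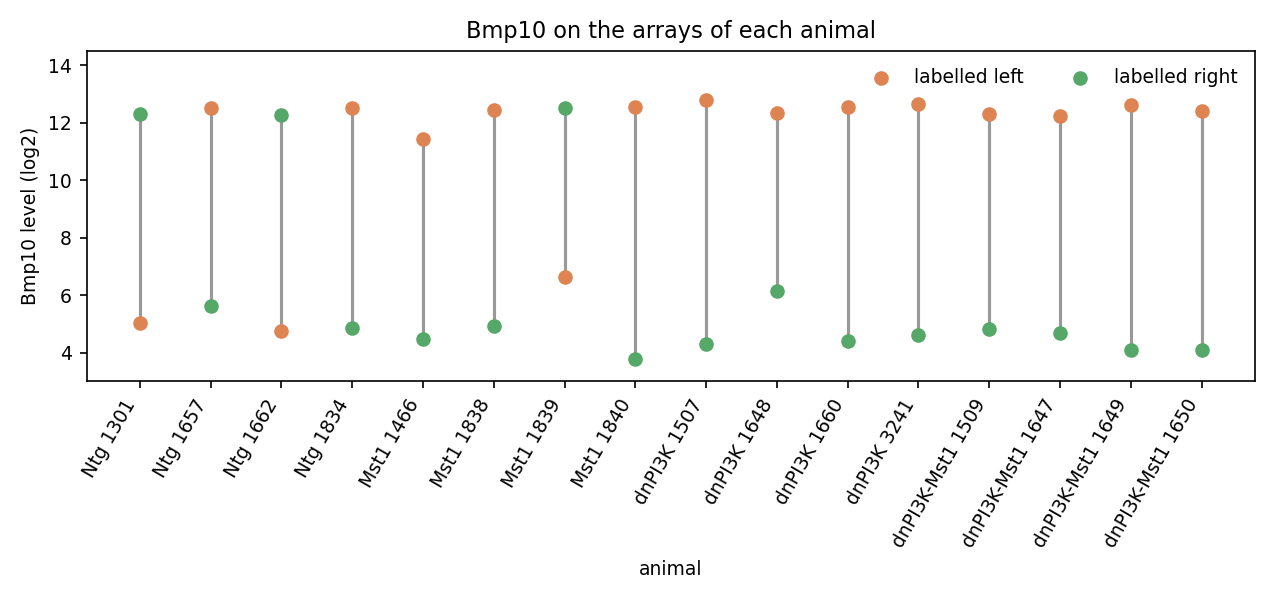
Level of Bmp10 (log2) on the 2 arrays of each of the 16 animals, joined by a line, with the array labelled left in 1 colour and that labelled right in another. The array labelled left is the higher in 13 animals and the array labelled right in Ntg 1301, Ntg 1662 and Mst1 1839.

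Genotype effects differed between the sides as labelled for 3 genes in dnPI3K against Ntg, each with a more positive change on arrays labelled right than on those labelled left: the immediate early gene Ier2 (1.03 ± 0.16, SE, n = 4 against 4, adjusted p = 0.03), Htra4 (0.80 ± 0.13, adjusted p = 0.03) and Dusp4 (1.08 ± 0.18, adjusted p = 0.038). At an unadjusted p under 0.05 the count was 1199. No gene was called by limma for Mst1 against Ntg, dnPI3K-Mst1 against Ntg or dnPI3K-Mst1 against Mst1, with 386, 425 and 292 at an unadjusted p under 0.05, though without Mst1 1839 the first of these gave 2. The 3 calls fell to 0 without Ntg 1301, Ntg 1657, Ntg 1662, dnPI3K 1507, dnPI3K 1648 or dnPI3K-Mst1 1649, to 1 without dnPI3K 3241 or dnPI3K-Mst1 1509, and came to 13 without Ntg 1834. They also depend on the model: all 32 arrays in 1 fit gave 4 genes with the animal as block and 1 without, and 0 of these were among the 3. With the trend over the mean level, chosen after seeing the data, 2 of the 3 were called, without Dusp4. Because 2 Ntg animals and 1 Mst1 animal have Bmp10 on the other side from the rest, these terms cannot be read as left against right atrium.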

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

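The tests of the 3 patterns weighed here were chosen after the patterns were seen, while those that regroup the animals were planned.

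The first pattern is the side labels. Bmp10 differed by at least 5.87 log2 between the arrays of every animal, with the array labelled left higher in 13 animals and the array labelled right higher in 3. Tissue of the other atrium in the same tube would narrow that gap, and the smallest gap of 5.87 argues against it, while genotype is argued against by 2 genotypes, Ntg and Mst1, that hold animals of both signs. Side labels exchanged in part of the animals would make many genes follow the signs of Bmp10, and 435 genes besides Bmp10 did so in at least 15 of 16 animals, where 7 genes followed the labels and 7.9 would by chance. This is consistent with labels exchanged in 13 of the animals, since adult mice express Bmp10 in the right atrium, rather than in the other 3, a hypothesis that rests on what is known of that gene, and no biological explanation other than genotype was tested.

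The second pattern is the fall of mitochondrial energy genes with the Mst1 transgene. Brightness of the probe sets is argued against, since the lowest median of 10000 random lists matched on level was -0.15 log2 against -0.65 for oxidative phosphorylation, and so are arrays that stand apart from the others, the median being -0.69 without their animals. A smaller share of cardiac myocytes would raise the markers of other cell types alike. In the 4 types with most of their markers above the median level of all genes the means changed unevenly, by 0.18 (fibroblast), 0.16 (smooth muscle and pericyte), 0.04 (macrophage and monocyte) and -0.25 (endothelial). The range was 0.43 log2 with exact permutation p = 0.029, the smallest that 4 animals against 4 allow. A smaller share alone therefore does not account for these markers. The test cannot decide whether a smaller share lowered the mitochondrial genes, since other cell types may change at the same time. The mean of the sarcomere list fell less than that of oxidative phosphorylation by 0.50 log2, and the exact permutation p of 0.057 leaves that test undecided. An effect of Mst1 on these genes may underlie the fall, a hypothesis found and tested on the same data.

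The third pattern is that some markers of other cell types were higher in dnPI3K-Mst1 than in Mst1, among them 7 of 15 endothelial and 4 of 14 smooth muscle markers. Arrays that stand apart from the others are argued against, since the endothelial median was 0.31 without their animals (0.36 with them) and 6 members were still called higher. A smaller share of cardiac myocytes would raise the markers of all other types alike. The same 4 types rose within 0.14 log2 of each other (exact permutation p = 0.54), the endothelial mean rose 0.22 log2 more than the neuron and glia markers above the median level of all genes, only 1 such marker lies above that level and the exact permutation p was 0.11, so this cannot be told apart. Against Ntg, the endothelial and mesothelium medians were -0.29 and -0.53 in Mst1 and 0.07 and 0.04 in dnPI3K-Mst1. By their medians these lists thus came back near the Ntg level. The fibroblast, macrophage and smooth muscle medians against Ntg were 0.03, 0 and -0.09 in Mst1 and 0.44, 0.4 and 0.23 in dnPI3K-Mst1. Growth or recruitment of the other cell types, or a change within them, may equally underlie the rise and was not tested. The rise also cannot be fully separated from what goes with the animal number. Only Mst1 1466 and dnPI3K-Mst1 1509 fall in the same number range.

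Regrouping the animals argues against chance alone for each of the 5 genotype comparisons, each with the smallest share that 35 splits allow. In 35 splits of the 8 animals compared, only 1, the real split, gave as many genes: 4084 for Mst1 against Ntg (highest other 263), 616 for dnPI3K against Ntg (2), 4658 for dnPI3K-Mst1 against Ntg (3), 532 for dnPI3K-Mst1 against Mst1 (63) and 3292 for dnPI3K-Mst1 against dnPI3K (0). Regrouping does not separate genotype from anything that goes with the animal number. In dnPI3K-Mst1 against Mst1 only Mst1 1466 and dnPI3K-Mst1 1509 fall in the same number range. With that range as a factor 310 genes were called there, and 211 of these were among the 532. For non-additivity 1 of 100 regroupings, the real one, gave 78, but another gave 75. The count was 54 without dnPI3K-Mst1 1509, 45 with the range of the animal number as a factor, 24 on arrays labelled right and 0 on those labelled left. The alternatives were not regrouped. Exchanging dnPI3K status also breaks up the dnPI3K effect itself, so this regrouping cannot decide whether chance gives the non-additivity count. For the side difference in dnPI3K against Ntg chance cannot be excluded (2 of 35, real 3, highest other 7). For 4 other side terms the real count was 0, which any regrouping reaches, so regrouping decides nothing: the mean of the genotypes (100 of 100, highest other 3) and the side differences in Mst1 against Ntg (35 of 35, highest other 257), dnPI3K-Mst1 against Ntg (35 of 35, highest other 1) and dnPI3K-Mst1 against Mst1 (35 of 35, highest other 0). For the sides within Ntg the 8 ways of exchanging them are too few for a share under 0.05, with a real count of 0 and 383 as the highest other. That count of 383 comes from exchanging the sides of Ntg 1657 and 1834, which equals exchanging Ntg 1301 and 1662, and it points to a structure of the samples. Which split gave the 257 was not examined.

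Of 600 groups of 4 animals examined for the 143 genes named, 48 held an animal apart from the other 3, where chance marks about 1 in 20 groups, or 30. Apart means that its gap is large for the range of the 4 values, so the gap in log2 can be small. Mst1 1466 accounts for 14 of them. It was lower than the other Mst1 animals in Ryr2 (10.32 against a mean of 11.31), Tead1 (9.06), Tnfrsf12a (8.46), Hspb1 (9.93), Xirp2 (11.42), Atp2a2 (12.29), Il6st (10.30), Stk38 (7.81) and Acaa2 (9.47). It was higher in Inmt (7.72), Aspn (10.25), Gja5 (8.91), Slc40a1 (5.96) and Ddx58 (7.41). Its left array was also the 1 least like the others. The animal dnPI3K-Mst1 1647 stood apart in 8 groups, higher in Thbs1 (10.90 against a mean of 9.49), Ier2 (7.53) and Fn1 (11.24) and lower in Ckm (6.12), Hrc (7.49), Ccdc68 (7.56), Kcnj3 (8.80) and Herpud1 (9.68).

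In Ntg, animal 1657 was high in Atf3 (8.19 against a mean of 5.91) and Ccn1 (9.12) and low in Aifm1 (8.68) and Cox7a1 (11.32 against a mean of 11.37). Animal 1301 was high in Fam171b (5.53), Ccdc68 (6.05), Pdgfra (9.23) and Thbs2 (7.37), 1662 was high in Kcnip2 (7.86) and low in Plppr5 (5.83), and 1834 was high in Cd74 (9.02). Among dnPI3K animals 1660 was high in Cpne5 (5.84), Muc15 (3.80) and Plppr5 (5.80), 1507 low in Dpep1 (8.95) and Echs1 (8.99), 1648 high in B3galt2 (4.68) and 3241 low in Nes (5.84). Mst1 1838 was low in Cd74 (8.01) and high in Tie1 (8.23), and Mst1 1839 had Bmp10 higher by 5.87 on the array labelled right. In dnPI3K-Mst1, animal 1650 was low in Nrg1 (9.10 against a mean of 9.21) and high in Shox2 (4.72) and Slc36a2 (6.60), and 1509 was high in Chrdl1 (7.72) and low in Stk4 (8.17).

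The Mst1 effect differed with and without dnPI3K for 21 of the genes named, by the test of non-additivity. The difference was negative for Adamts8 (-2.18), Plet1 (-1.38, but 0.08 on arrays labelled left alone), Lgals3 (-1.27), Ndnf (-1.27), Nppb (-1.16), Nap1l5 (-1.15), Nt5e (-1.14), Phlda1 (-1.03), Kcnh7 (-0.99), Marchf11 (-0.86) and Mt2 (-0.85). It was positive for Lrtm1 (1.76), Itga8 (1.32), Mrgprh (1.28), Slc36a2 (1.18), Itgb6 (1.05), Slc17a7 (1.04), Ednrb (0.83), Notch3 (0.83), Igsf1 (0.82) and Sprr1a (0.78). Slc36a2 is an adipocyte marker, and the fat genes on arrays of dnPI3K-Mst1 1650 and Ntg 1301 may add to its difference. For Lrtm1, Mrgprh, Itgb6 and Igsf1 the sum of both single effects, 3.36, 3.48, 3.79 and 4.08 log2, lies below 4.48, the level under which genes were left out, so the floor of the signal alone can produce a positive difference. The dnPI3K effect differed between arrays labelled right and left for Dusp4 (1.08), Ier2 (1.03) and Htra4 (0.80).

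Probe sets with no single gene symbol, 8186 above the same filter, also changed: 347 in Mst1 against Ntg, 19 in dnPI3K against Ntg, 455 in dnPI3K-Mst1 against Ntg, 4 in dnPI3K-Mst1 against Mst1, 192 in dnPI3K-Mst1 against dnPI3K and 1 for non-additivity.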

How the results depend on the processing

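Leaving out the arrays that stood apart, or their animals, and the trend over the mean level were chosen after seeing the data, and the other alternatives were planned. The 4 animals per genotype limit the precision, and the cause of the changes below was not tested. A fit on 1 labelled side uses fewer arrays and also mixes the sides as told by Bmp10. The array labelled left holds the higher Bmp10 level in every dnPI3K and dnPI3K-Mst1 animal, but not in Ntg 1301, Ntg 1662 and Mst1 1839. Counts not given here stayed within 1.5 times the reported ones, which does not say that the genes are the same: the 4 genes of the block fit for the side difference in dnPI3K against Ntg include 0 of the 3 reported. With only arrays labelled left there were 2129 calls in Mst1 against Ntg, 105 in dnPI3K against Ntg, 2417 in dnPI3K-Mst1 against Ntg, 74 in dnPI3K-Mst1 against Mst1, 1763 in dnPI3K-Mst1 against dnPI3K and 0 for non-additivity by limma. With only arrays labelled right there were 339 in dnPI3K against Ntg, 102 in dnPI3K-Mst1 against Mst1, 2187 in dnPI3K-Mst1 against dnPI3K and 24 for non-additivity. The Mst1 effects without and with dnPI3K then correlated at 0.72 (left) and 0.74 (right). Array weights gave 945, 1686 and 358 for dnPI3K against Ntg, dnPI3K-Mst1 against Mst1 and non-additivity, and 87 for the sides over the genotypes. A fit of 32 arrays with no block gave 928, 899, 186 and 86 for the same terms and 1 for the side difference in dnPI3K against Ntg. With the animal as block the sides over the genotypes gave 113, no trend gave 1 and the trend over the mean level gave 1. Leaving out the animals of arrays that stood apart gave 278 for dnPI3K against Ntg, 903 for dnPI3K-Mst1 against Mst1 and 0 for the side difference in dnPI3K against Ntg. Leaving out those arrays with the animal as block gave 962 for dnPI3K-Mst1 against Mst1, 46 for the sides over the genotypes and 1 for that side difference. Only the 2 genotypes compared gave 334 in dnPI3K-Mst1 against Mst1. The range of the animal number as a factor gave 310 there, 45 for non-additivity and 1 for the side difference in dnPI3K against Ntg, for which no filter gave 1 and quantile normalization 5.

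Signs reversed for Lcn2 (-0.055) and Flt1 (0.024) in dnPI3K-Mst1 against dnPI3K and Plet1 (0.076) for non-additivity on arrays labelled left, and for Pvalb (-0.209) in dnPI3K-Mst1 against Ntg and Hamp2 (0.054) in dnPI3K-Mst1 against dnPI3K on arrays labelled right. Without the animals of arrays that stood apart, camera called the opposite direction for lung markers over the sides (adjusted p = 0.0096) and oxidative phosphorylation in the side difference of Mst1 against Ntg (adjusted p = 0.013). Leaving out 1 animal at a time gave 3352 to 4806 calls in Mst1 against Ntg, 378 to 1013 in dnPI3K against Ntg, 3953 to 5447 in dnPI3K-Mst1 against Ntg, 249 to 765 in dnPI3K-Mst1 against Mst1, 2652 to 4008 in dnPI3K-Mst1 against dnPI3K and 54 to 207 for non-additivity. For the sides it gave 0 to 0 in Ntg and 0 to 277 over the genotypes (277 without Mst1 1839, 2 without Ntg 1301). The side differences gave 0 to 2 in Mst1 against Ntg, 0 to 13 in dnPI3K against Ntg and 0 in the others. The 3 correlations ranged over 0.28 to 0.39 for dnPI3K, 0.79 to 0.83 for Mst1 and 0.38 to 0.47 with shared Ntg. Camera calls ended in 13 of 240 such refits of the lists called in Mst1 against Ntg (heat shock genes and Hippo members 4 each, mesothelium 3 and endothelial markers 2), in 20 of 208 in dnPI3K against Ntg (ion channels 6, fibroblast 4 and skeletal muscle markers 3 among them) and in 6 of 256 in dnPI3K-Mst1 against Ntg (adipocyte markers 3 among them). They ended in 40 of 384 in dnPI3K-Mst1 against Mst1 (PI3K and insulin signalling 10, sinoatrial node 8, Hippo members 7, cytokines 6, sarcomere 3 and MHC class II 2 among them), 2 of 240 in dnPI3K-Mst1 against dnPI3K and 14 of 240 for non-additivity. Camera's direction reversed in 5 lists that were not called with all animals. For the sides in Ntg these were adipocyte markers (adjusted p = 0.027 without Ntg 1301, range 0.017 to 0.79) and MHC class II (0.017 without Ntg 1662, range to 1). Over the sides it was cell cycle (0.026 without dnPI3K-Mst1 1647, range to 0.97). In the side difference of dnPI3K-Mst1 against Ntg these were macrophage markers (0.014 without dnPI3K-Mst1 1647, range to 0.79) and fatty acid oxidation (0.025 without dnPI3K-Mst1 1650, range to 0.96). Over all single omissions, 8623 of 9280 called values of named genes stayed called, 657 were no longer called and 0 reversed. Of 577 such values with all animals, arrays labelled left alone kept 366 and lost 208, and arrays labelled right alone kept 406 and lost 169, while leaving out the animals of arrays that stood apart lost 83 of 580.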

Other observations

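The genes that went with Bmp10 across sides were looked at after the pattern was seen. Cxcl13, a lymphoid chemokine, was higher on the side of Bmp10 in 16 of 16 animals by a median of 4.26 log2, the macrophage receptor Vsig4 by 3.90, the Langerhans cell gene Cd207 by 3.41, A2m by 2.28 and Adh6b by 2.18, and Hamp in 15 of 16 by 1.93. On the other side were Mmrn1 (-2.40), Mapk10 (-1.53), Pi16 and Prg4 (-1.38 each) and the macrophage lectin Clec10a (-1.26), each lower on the side of Bmp10 in 16 of 16 animals. The pacemaker genes Hcn4 (0.60) and Tbx3 (0.28) went with Bmp10 in 14 of 16.

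Brown fat and adipocyte genes stood out on 2 arrays. Ucp1, with a median of 4.55 over 32 arrays, reached 8.93 on dnPI3K-Mst1 1650 right and 8.38 on Ntg 1301 left, with 5.09 the third highest. Adipoq reached 7.79 and 7.85 there against a median of 3.90. The ventricular gene Myl2, with a median of 5.21, reached 10.70 on dnPI3K 1648 left and 8.15 on Ntg 1301 right, and Alas2 reached 9.31 on Mst1 1466 right against 6.48. Lung Sftpc did not exceed 4.71.

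Lists with no camera call in the 6 genotype terms include T and B lymphocyte markers, with medians of 0.11 in Mst1 and 0.08 in dnPI3K against Ntg and 2 of 8 members higher in dnPI3K-Mst1 against Ntg and 1 against dnPI3K, and neutrophil markers, with medians of -0.03, 0.03 and 0.01 in these comparisons. Of 5 neutrophil markers 1 was higher and 1 lower in Mst1 against Ntg and in dnPI3K-Mst1 against dnPI3K, and 1 was higher in dnPI3K against Ntg and in dnPI3K-Mst1 against Mst1. Lung and thymus markers had medians of 0.00 and -0.05 in Mst1, with 1 of 6 thymus markers lower, and cardiac neuron and glia markers -0.08, with 1 of 14 higher and 2 lower. Ventricular myocardium markers had 3 of 10 lower and 1 higher in Mst1 (camera adjusted p = 0.13), and 4 lower and 2 higher in dnPI3K-Mst1 against dnPI3K (0.052). The reference groups of these comparisons hold Ntg 1301 and dnPI3K 1648, on whose arrays Myl2 stood out. Circadian clock genes had 4 of 16 lower and 1 higher in Mst1 (0.72). Erythroid markers, with 2 members, had a median of -0.13 in Mst1, and the 3 sex-linked genes -0.06. Renin-angiotensin, adrenergic and peptide signalling genes had 3 of 20 higher and 7 lower in Mst1 (0.13) and 3 higher and 1 lower in dnPI3K-Mst1 against Mst1 (0.0045, and adjusted p = 0.32 with an estimated correlation).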
